A study of Arabidopsis thaliana with 12 samples.

How the data were processed

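Total RNA of whole seedlings was extracted with a Qiagen kit and labelled with biotin by the Affymetrix in vitro transcription kit, per the labels' protocols. Per the labels, plants grew on MS medium in a growth room at 20 °C with 16 h of light and 8 h of dark, after 4 days in a fridge. The deposited values are intensity on a linear scale, the MAS5 signal of 22810 probe sets on each of 12 arrays. MAS5 and GCOS are named in the submitters' processing notes, and their versions and settings are not given in the sources used here. The mean signal after trimming 2% from each end was 100.0 on every array, so the authors' values were taken as scaled, and no further scaling was applied for the values reported. No pair of arrays held identical values (0 pairs), and 182 values were 0. For arrays no read depth exists; the median signal per array was 34.5 to 39.3.

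Gene names came from GEO's platform table for these probe sets. It listed 14016 of them, 13513 with 1 gene and 503 with several; 8794 had no gene listed there and stay unnamed. Of the 13513, 13436 matched a gene in the RefSeq table of assembly TAIR10.1, used for names and neighbours only, and 77 did not. Probe sets with several genes or none were not named. The 64 Affymetrix control probe sets were used for array quality and left out of the tests.

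Signals were analysed as log2(signal + 1.6), where 1.6 is the 10th percentile of all values, so fold changes of low signals are understated; a size that rests on signals under the filter level below is uncertain, in every comparison. Probe sets were kept if their mean over the 12 arrays reached the 40th percentile, a signal of 21.9, which left 13648. limma 3.58.1 in R 4.3.3 fitted line and temperature (5 residual degrees of freedom) with an intensity trend in eBayes. Benjamini-Hochberg adjusted p under 0.05 was the threshold. Each line was compared with the mean of Col-0 and Col-aeq over both temperatures. The cold change was compared between classes of lines on the 6 within-line differences (3 residual degrees of freedom), with 3 mutant lines, 1 overexpressor and 2 control lines. SE values are limma's moderated ones. Tables and figures used Python 3.11.15, pandas 2.3.3, NumPy 2.4.6 and matplotlib 3.10.9.

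The design, the rule for named genes, 17 gene lists with 255 genes and most alternatives were fixed before the data were examined. The rule took, for cold, the 8 largest rises and falls of single-gene probe sets that passed with the same sign in 6 lines, the 3 members of each fixed list with the lowest adjusted p, and for each line the 5 largest rises and falls with the same sign at both temperatures. Where no probe set passed, it took the 3 with the lowest p. Members of lists given as further examples, and unnamed probe sets, were chosen after their values were seen. Of the 255 genes, 37 had a named probe set and 29 were tested. The lists for abscisic acid, jasmonate, salicylate and defence, calcium and touch, and seed storage had 0 tested members. Therefore 25 lists were added from gene names after the annotation was seen, plus 1 list of root markers. camera with a preset correlation of 0.01 tested lists with at least 5 members (22 lists for cold), adjusted within each contrast. No list call in any comparison held with an estimated correlation. A lost call does not by itself show correlated genes. The list of SWEET sugar transporters in the cold had an estimated correlation of −0.0899, below the preset. Its camera adjusted p still went from 0.0381 to 0.384.

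On simulated data with 200 of 13648 probe sets changed, over 5 runs, the cold test recovered 59.4% of log2 changes of 0.5, 99.1% of 1 and 100% of 2, and the fad2 test 2.8%, 88% and 100%. In the data many more probe sets passed (4538 for cold and 1289 for fad2), and the simulation gave every array the same spread for a gene. Recovery in the data may thus differ, most of all for small changes. Alternatives were quantile normalization, centring on the median, a floor at the 1st percentile, a pseudocount at the 25th percentile, no filter, a filter at the 60th percentile, no intensity trend, no line block, array weights, either control line alone, other classes of lines, and leaving out each array or line. Runs without the Col-aeq arrays were added after the quality values were seen. The scalings moved the median of all genes by at most 0.1 on the log2 scale. Nothing was reported from probe sets under the filter, except where the filter was lifted as an alternative.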

Results

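The series measured transcripts in whole Arabidopsis thaliana seedlings, at growth stage 1.02, with 12 Affymetrix ATH1 arrays. Its title concerns the part that membrane fluidity plays in the perception of low temperature. There were 6 lines, each with 1 array from ambient temperature and 1 from the cold. Col-0 and Col-aeq, a Columbia line that carries the apoaequorin calcium reporter, were the 2 control lines. The 3 mutant lines were fab1, which lowers the elongation of palmitate, fad2, which lacks the main oleate desaturase of the endoplasmic reticulum, and the triple mutant fad3/7/8, which lacks linoleate desaturases and carries apoaequorin per its titles. The line 35S-FAD3 overexpressed a linoleate desaturase. Its 2 arrays are named for 35S-FAD3 in the titles and for apoaequorin alone in the genotype label; they were grouped by the title, and every value for this line rests on that choice. The genes FAB1, FAD2, FAD3, FAD7 and FAD8 had no named probe set in the table used here, so the genotypes could not be checked on the arrays. The temperature and length of the cold treatment are not given in the sources used here. All 12 arrays are labelled as replicate 1, and the number of arrays limits the precision. For cold and for classes of lines, p-values measure how far the cold change differed between lines. The test of a single line used the spread left by line and temperature. Whatever the 2 arrays of a line shared went into its difference, so these p-values do not measure spread between separate growths.

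The Col-aeq ambient array stood apart in its control probe sets. Its signal for actin was 7.00 times as high at the 3' end as at the 5' end, against 1.96 to 2.21 on the other ambient arrays, and for GAPDH the ratio was 1.87 against 0.972 to 1.05. Its 25S rRNA signal was 2463, against 134 to 312, and the Col-aeq cold array had 849. The arrays correlated with one another at r of 0.932 or more across probe sets, which are not independent replicates. The control mean for each line below used the Col-aeq arrays, so the number of probe sets that passed for cold and for each altered line is also given without both of them, an alternative chosen after these values were seen.

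**Figure D1:**
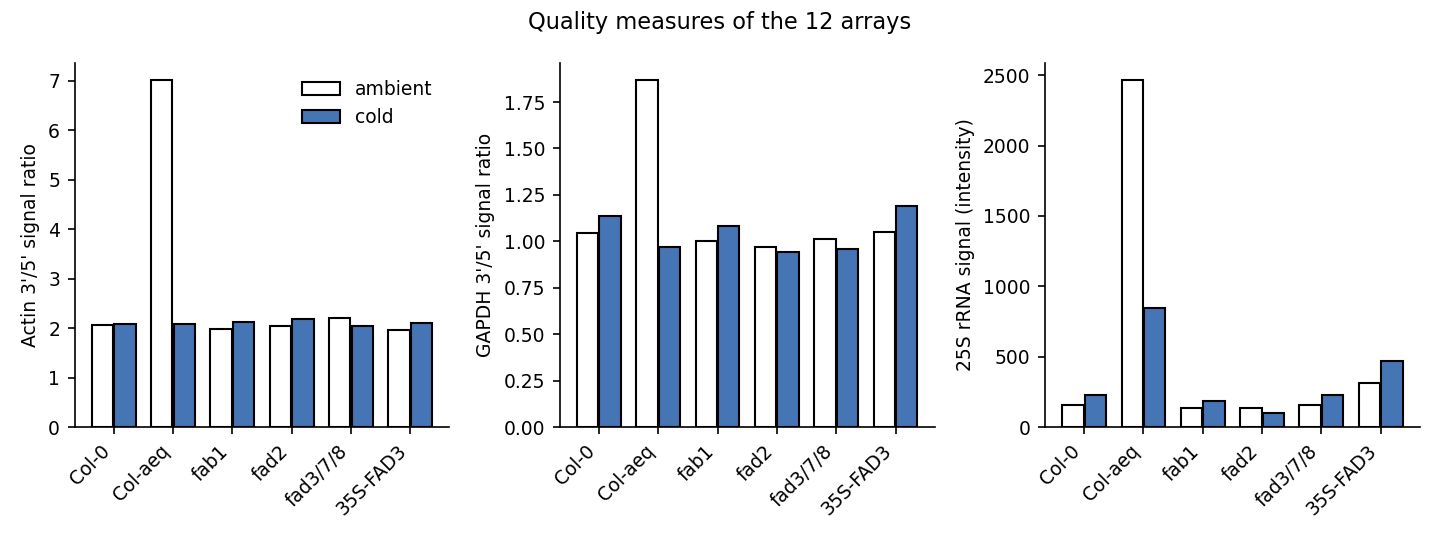
Bars give, for each of the 12 arrays, the 3' to 5' signal ratio of actin and of GAPDH and the 25S rRNA signal as MAS5 intensity, with ambient arrays in white and cold arrays in blue. The Col-aeq ambient array lies at 7.00, 1.87 and 2463, above the other 11 arrays on each measure.

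The first comparison asked what the cold did in all 6 lines. Cold raised the known cold-response genes strongly. COR27, a cold-regulated gene tied to the circadian clock, rose by 4.81 on the log2 scale (SE 0.337), and its relative AT4G33980, known as COR28, rose by 4.35 (SE 0.219). STZ, a zinc-finger repressor of the stress response, rose by 3.95 (SE 0.12, 15.4-fold). It was the single tested member of the list of early cold transcription factors; CBF1, CBF2 and CBF3 had no named probe set. Of the COR genes fixed as a list, 6 of the 6 tested rose, and so did 6 when adjusted over the list alone. Among them the dehydrins LTI30 and COR47 rose by 2.27 (SE 0.0722) and 1.40 (SE 0.0841), and COR15A and COR15B, which protect chloroplasts in freezing, by 2.51 (SE 0.167) and 2.79 (SE 0.235). Other large rises were those of AT4G36010, a thaumatin family gene (signals of 13.4 to 49.2 at ambient temperature and 416 to 828 in the cold over 6 lines), AT1G51090 (4.35, SE 0.133), AT1G11210 (4.07, SE 0.168), AT1G48100, a pectin lyase family gene (3.59, SE 0.111), and AT1G07050 (3.34, SE 0.148). Of the probe sets without a listed gene, the 2 with the largest rises went up by 5.80 (SE 0.155) and 5.41 (SE 0.246). Ambient signals were 1.4 to 31.1 for COR27, 4.4 to 51.3 for AT4G33980 and 5.7 to 25.2 for AT1G07050, mostly under the filter level of 21.9, so the sizes of these rises are uncertain.

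The largest falls among named genes were those of AT1G33055, by −3.72 on the log2 scale (SE 0.354), AT1G23390, an F-box gene that acts on chalcone synthase (−2.95, SE 0.0832), AT2G20670 (−2.79, SE 0.168), AT2G03750 (−2.74, SE 0.109) and AT1G26800, a RING-type ubiquitin ligase gene (−2.70, SE 0.224). AT1G14200 (−2.65, SE 0.145), AT3G26510 (−2.63, SE 0.101) and AT5G19120 (−2.54, SE 0.125) fell too. Cold signals of AT1G33055 (2.6 to 15), AT1G26800 (5.5 to 21.7) and AT1G14200 (9.1 to 17.9) lay under that level as well, which makes the sizes of these falls uncertain.

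**Figure D2:**
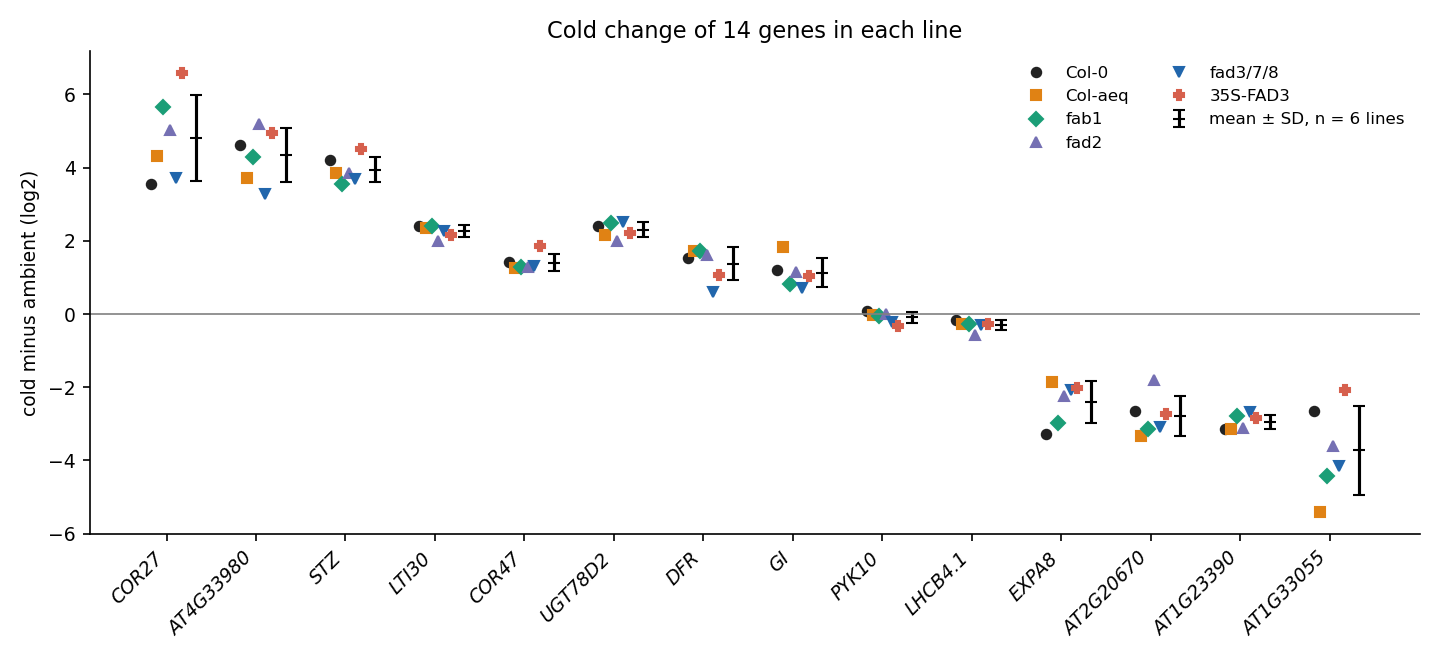
Each symbol is the cold minus ambient log2 difference of 1 line for 1 of 14 genes, and bars give the mean ± SD over 6 lines. COR27 spans 3.56 to 6.59 and AT1G33055 spans −5.41 to −2.09, spans that rest on signals near the floor, while LTI30 lies between 1.99 and 2.41 in the 6 lines.

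Single genes of several smaller fixed lists passed as well. In the phenylpropanoid and anthocyanin list, 3 of 3 tested genes rose (3 adjusted over the list alone). They were UGT78D2, a flavonoid glucosyltransferase (2.30, SE 0.0869), DFR, which makes anthocyanin precursors (1.38, SE 0.153), and UF3GT (0.78, SE 0.155). GI, a clock gene, rose by 1.13 (SE 0.127) as the single tested member of its list (1 adjusted over the list alone). Of the nucleolar genes, 2 of 2 rose (2 adjusted over the list alone), AT5G14520 by 0.78 (SE 0.1) and AT3G05060 by 0.61 (SE 0.131). EXPA8, a cell-wall expansin, fell by 2.41 (SE 0.175), while HAT2 changed by 0.15 (SE 0.0867, adjusted p = 0.205), so 1 of 2 tested growth genes passed (1 adjusted over the list alone). LHCB4.1, of the photosystem II antenna, fell by 0.31 (SE 0.0606), and RCA, Rubisco activase, stood at −0.10 (SE 0.052, adjusted p = 0.171), which made 1 of 2 photosynthesis genes (1 adjusted over the list alone). Of 2 genes of protein folding in the endoplasmic reticulum, the co-chaperone ATERDJ3B fell by 0.32 (SE 0.0758) and BZIP60 stood at 0.20 (SE 0.0849, adjusted p = 0.0992); 2 passed when adjusted over the list alone.

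The tested genes of the fixed lipid list and the fixed root list did not pass the test. The acyl carrier protein thioesterases FATB and FaTA stood at 0.09 (SE 0.0949, adjusted p = 0.492) and 0.03 (SE 0.153, adjusted p = 0.908), and 0 of 2 passed adjusted over the list alone. Of the fixed root list, 0 of 4 passed (0 adjusted over the list alone), with PYK10, an abundant root beta-glucosidase, at −0.09 (SE 0.0644, adjusted p = 0.292), AT5G17820 at −0.15 (SE 0.135, adjusted p = 0.423) and EXPA18 at −0.24 (SE 0.159, adjusted p = 0.271). EXPA18 passed without the Col-aeq line (−0.40, adjusted p = 0.0291). In a longer list of 15 root markers, 2 fell, AT4G26010 (−0.72, SE 0.203, adjusted p = 0.019) and AT4G30170 (−0.41, SE 0.103, adjusted p = 0.00981), and 5 fell without Col-aeq. The heat shock gene AT5G48570 stood at −0.53 (SE 0.209, adjusted p = 0.0744; 1 adjusted over the list alone), and without the Col-0 line it passed at −0.78 (adjusted p = 0.00226). Of 3 reference genes, AT4G34270 fell by 0.33 (SE 0.0975, adjusted p = 0.0238), AT2G28390 rose by 0.41 (SE 0.141, adjusted p = 0.0438) and PEX4 stood at 0.10 (SE 0.0721, adjusted p = 0.302); 2 passed adjusted over the list alone. AT4G34270 no longer passed without Col-0 (adjusted p = 0.0765) or fab1 (0.0606). AT2G28390 no longer passed without Col-0 (0.0531), Col-aeq (0.0688), fad2 (0.0862), 35S-FAD3 (0.0712) or fad3/7/8 (0.126), nor without the signal filter (0.0781).

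Of 13648 tested probe sets, 4538 passed limma's test for cold against ambient, 2042 higher and 2496 lower in the cold, and 3847 of the 4538 had the same sign in 6 of 6 lines. Without both Col-aeq arrays 5295 passed. Of the 4538 calls, 624 changed over 2-fold, 377 up and 247 down. In limma's camera test of lists, the COR genes ranked up (median 2.65, adjusted p = 1.99e-08; adjusted p = 0.165 with an estimated correlation). Lists built from gene names, after the annotation was seen and before any test, were tested too. Of 9 tested ATG8 autophagy genes, 7 fell, led by ATG8E (−1.32, SE 0.128) and ATG8F (−1.01, SE 0.0857), with a list median of −0.61 (adjusted p = 0.00022; adjusted p = 0.384 with an estimated correlation). The Col-aeq line, whose ambient array stood apart, had a median ATG8 change of −1.03, against −0.63 to −0.45 in the other lines. Among 27 nuclear genes of photosynthesis and chlorophyll synthesis, 11 fell and 1 rose (median −0.20, adjusted p = 0.00117; adjusted p = 0.384 with an estimated correlation); under quantile normalization 10 fell. NdhS, of the plastid NDH complex, fell by 0.84 (SE 0.115), and HEME1 and HEME2, of tetrapyrrole synthesis, by 0.58 (SE 0.106) and 0.47 (SE 0.0638).

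The fad2 line differed most from the control lines by count. AT3G13610, the scopoletin synthesis gene F6'H1, was 2.48 higher on the log2 scale in fad2 (SE 0.231, 5.59-fold), with signals of 680 and 640 against 62.6 to 148 on the other 10 arrays. The peroxidase gene AT4G36430 was 2.13 higher (SE 0.228), AT3G02480, of the late embryogenesis abundant proteins, 2.14 (SE 0.39), the pectin methylesterase ATPMEPCRB 2.08 (SE 0.263) and AT1G52060, of the mannose-binding lectins, 2.07 (SE 0.185). AT2G38240, an oxygenase that hydroxylates jasmonate, was lower by −3.95 (SE 0.41). Also lower were the fructokinase-like AT3G59480 (−2.50, SE 0.34), the bHLH gene AT1G10585 (−2.13, SE 0.283), AT5G04080 (−1.85, SE 0.358) and the pyruvate kinase gene AT3G49160 (−1.73, SE 0.18). In fad2 the signals were 3.6 and 4.7 for AT2G38240, 13.1 and 1.3 for AT3G59480 and 20.9 and 4.0 for AT5G04080, and AT1G10585 (11.5 at ambient temperature) and AT3G49160 (17 in the cold) were low on 1 array. Control signals were 13.3 to 18.4 for ATPMEPCRB and 21.1 to 22.8 for AT1G52060. With signals near or under the filter level, all of these sizes are uncertain.

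Some genes of cell-wall loosening and some root markers were higher in fad2. Of 15 tested expansins and xyloglucan enzymes, 4 were higher and 1 lower at the threshold, with XTH19 up by 2.00 (SE 0.235), EXPA18 by 0.96 (SE 0.238) and EXGT-A3 down at −0.63 (SE 0.123); the list median was 0.53 (camera adjusted p = 0.000812; adjusted p = 0.354 with an estimated correlation), and without Col-aeq 6 were higher and 1 lower. Of 5 endo-1,4-glucanases, 2 were higher, GH9B13 by 1.96 (SE 0.198) and GH9C2 by 1.30 (SE 0.364), with a median of 0.84 (adjusted p = 0.001; adjusted p = 0.354 with an estimated correlation), and 3 were higher without Col-aeq. In the fixed root list, AT5G17820, a root peroxidase, and EXPA18 were higher by 1.11 (SE 0.202) and 0.96, 2 of 4 (3 adjusted over the list alone), while PYK10 stood at −0.14 (SE 0.0966, adjusted p = 0.401). A longer list of 46 root markers was written after 12 leading fad2 genes had been seen and without them. Of these, 19 had a probe set and 15 were tested, with 8 higher and 0 lower. Control signals of some lay near the filter level, such as 14.4 to 23 for AT5G15180. The tested list holds the 4 genes of the fixed root list and 2 of the expansin list. EXPA18 thus counts in all 3 lists, and these are not separate evidence. It had a median of 0.78 (adjusted p = 3.43e-07; adjusted p = 0.354 with an estimated correlation); 7 were higher under quantile normalization or median centring and 10 without Col-aeq. DFR and UF3GT were both higher, by 1.13 (SE 0.23 and 0.233), 2 of the 3 phenylpropanoid genes (2 adjusted over the list alone); without Col-aeq 1 of the 3 was higher and 1 lower, and the list median was 0.78 against 1.13. Of 6 COR genes 0 passed (0 adjusted over the list alone; median −0.07).

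**Figure D3:**
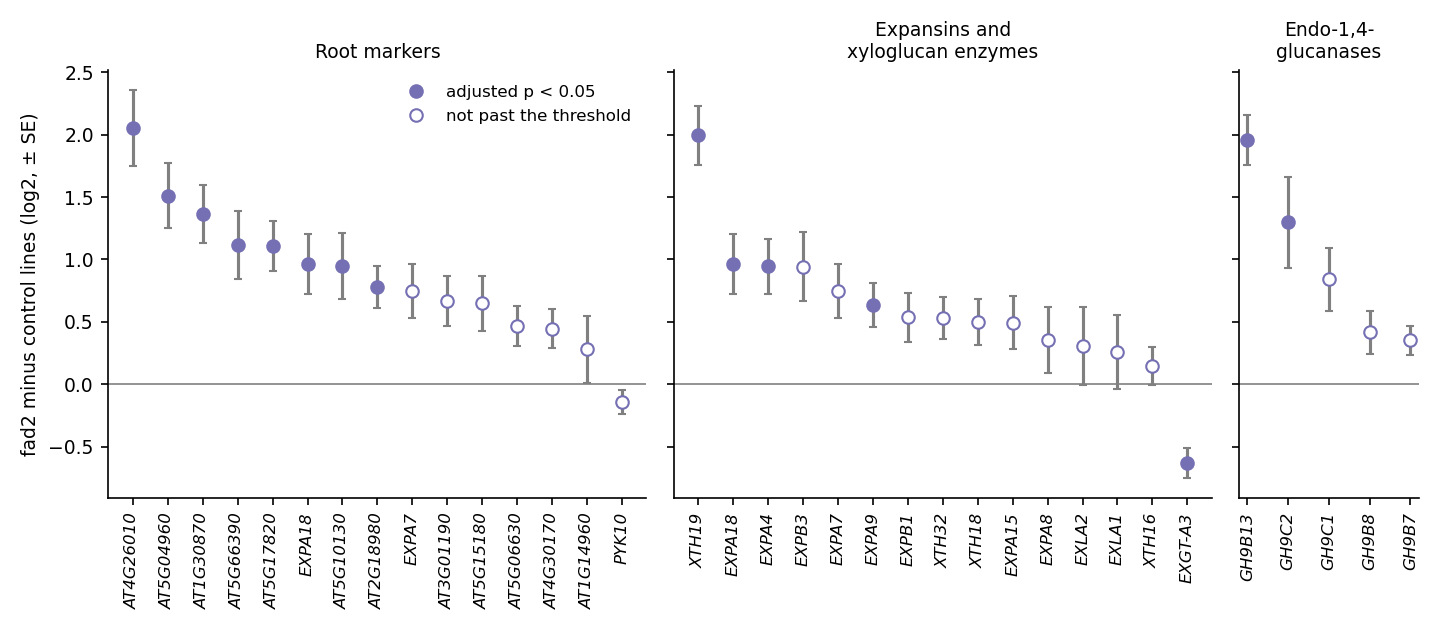
Points give the log2 difference of fad2 from the mean of the control lines with its SE for the members of 3 lists; filled points passed limma's test. AT4G26010 lies at 2.06 and PYK10 at −0.14 among the root markers, and EXGT-A3 at −0.63 is the 1 filled point below 0.

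For fad2, 1289 of 13648 probe sets passed limma's test, 705 higher and 584 lower, with 252 over 2-fold. The count was 53 without the fad2 ambient array, 154 without the fad2 cold array, 429 without Col-0 ambient, 611 without Col-0 cold and 3391 without Col-aeq cold, and 1585 without both Col-aeq arrays, with 986 shared. AT3G02480 no longer passed without the fad2 ambient (adjusted p = 0.121) or cold array (0.105), ATPMEPCRB and AT1G10585 without fad2 ambient (both 0.0736), nor AT5G04080 without fad2 cold (0.121).

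In 35S-FAD3, the sugar transporter SWEET1 was 1.64 higher than in the control lines (SE 0.163, 3.11-fold), with signals of 438 and 557 against 107 to 264 elsewhere. AT1G12845 was higher by 1.39 (SE 0.172), AT1G11850 by 1.38 (SE 0.149), AT3G25150 by 1.33 (SE 0.163) and the GDSL lipase gene AT1G33811 by 1.21 (SE 0.164). AT2G44210 was lower by −2.70 (SE 0.248), the jasmonate oxygenase gene AT5G05600 by −2.20 (SE 0.267), AT1G10585 by −2.08 (SE 0.283), the protein kinase gene AT3G17750 by −1.26 (SE 0.19) and AT4G07820 by −1.14 (SE 0.178). A probe set without a listed gene was lower (adjusted p = 1.86e-05), with signals of 18 and 9.9 against 231 to 425 in the control lines. The 35S-FAD3 signals of AT1G10585 (16 and 21.9), and the cold ones of AT2G44210 (21.5) and AT4G07820 (20.8), were near or under the filter level too, so these sizes are uncertain. AT3G25150 had signals of 93.8 and 92.6 in 35S-FAD3, below the 123 and 113 of Col-0, so its difference came from the 13.8 and 7.7 of Col-aeq in the control mean. No COR gene passed (0 of 6, and 1 adjusted over the list alone), while the COR list ranked lower by camera. Its median was −0.37 (adjusted p = 0.00654, 0.345 with an estimated correlation, 0.801 without Col-aeq). Other lists ranked by camera too. Among them, expansins and xyloglucan enzymes were higher, as in fad2 (median 0.40, adjusted p = 0.0015, 0.00964 without Col-aeq). Nuclear photosynthesis genes were higher (0.14, 0.000405, 5.08e-09) and RNA polymerase subunits lower (−0.35, 0.00184, 0.00476). No member of these 3 lists passed alone, and each list stood at 0.345 with an estimated correlation.

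By limma, 28 probe sets passed for 35S-FAD3, 12 higher and 16 lower, beside 1702 at an unadjusted p under 0.05. The count was 7 without its ambient array, 3 without its cold array, 14 without Col-0 ambient, 43 without Col-aeq ambient, 1679 without Col-aeq cold and 314 without both Col-aeq arrays, with 26 shared. Of the 10 named genes, 7 no longer passed without its ambient array (adjusted p 0.0584 to 0.295, SWEET1 at 0.0762), 8 without its cold array (0.0645 to 0.44), 4 without Col-0 ambient (0.0731 to 0.13) and 3 without Col-0 cold (0.0575 to 0.1). AT2G44210 passed under each of these. Without the signal filter AT1G10585 (0.0667), AT3G17750 (0.0842) and AT4G07820 (0.11) no longer passed.

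Few probe sets passed for fab1 and fad3/7/8 against the control mean, and both numbers depended on the Col-aeq arrays. AT3G25150, a nuclear transport factor 2 family gene, was higher by 1.66 in fab1 (SE 0.163, adjusted p = 0.00464) and by 1.51 in fad3/7/8 (SE 0.163, adjusted p = 0.0112). Its signals were 144 and 95.9 in fab1, 116 and 97.5 in fad3/7/8 and 123 and 113 in Col-0, but 13.8 and 7.7 in Col-aeq, so the difference came from the Col-aeq part of the control mean. Another probe set without a listed gene was lower both in fab1 (adjusted p = 0.000866; signals of 24.7 and 15.7) and in fad3/7/8 (adjusted p = 0.00115; 21.2 and 20.2), against 91.8 to 121 in the control lines. Of 6 COR genes, 0 passed in fab1 (0 adjusted over the list alone), while the list ranked lower by camera (median −0.30, adjusted p = 0.0226; adjusted p = 0.392 with an estimated correlation, 0.922 without Col-aeq). For fad3/7/8, 0 passed (1 adjusted over the list alone; camera adjusted p = 0.139). Without Col-aeq 1 passed in fad3/7/8 by limma, AT4G33980 (2.47, SE 0.342, adjusted p = 0.00621). Its ambient and cold signals were 4.4 and 146.8 in Col-0, the lowest of the 6 lines at each temperature, against 51.3 and 515.5 in fad3/7/8. The low Col-0 ambient signal makes the size uncertain. The COR list without Col-aeq had a camera adjusted p of 0.0277, with the preset correlation alone.

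With limma, 2 probe sets passed for fab1 (1 higher, 1 lower; 847 at an unadjusted p under 0.05) and 4 for fad3/7/8 (3 higher, 1 lower; 1702). Centring each array on its median split the 4 into 2 and 2. The fab1 count was 1 without either fab1 array, 5 without Col-aeq ambient, 745 without Col-aeq cold and 14 without both Col-aeq arrays. The fad3/7/8 count was 2 without its ambient array, 0 without its cold array, 2 without either Col-0 array, 19 without Col-aeq ambient, 1810 without Col-aeq cold and 691 without both, when the single control, Col-0, lacked the apoaequorin of fad3/7/8. AT3G25150 no longer passed in fab1 without the fab1 ambient (adjusted p = 0.374) or cold array (0.0633), nor in fad3/7/8 without its ambient (0.26), its cold (0.147) or the Col-0 ambient array (0.0691).

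The control lines were compared to set a rough scale for these counts. This contrast set 2 arrays against 2, with a median SE of 0.189, against 0.164 for each altered line. AT3G25150 was lower in Col-aeq than in Col-0 by −3.32 (SE 0.188), with Col-aeq signals under the filter level at both temperatures. Higher in Col-aeq than in Col-0 were the acid phosphatase family gene AT2G39920 (1.83, SE 0.215), the Hsp70 exchange factor gene Fes1B (1.42, SE 0.214), AT4G32340 (1.37, SE 0.205), the dioxygenase gene AT5G43440 (1.23, SE 0.178) and AT1G70820 (1.19, SE 0.155). For each of these 5 genes the Col-0 signal was below that of every other line at both temperatures. For AT1G70820 the ambient signal was 390 in Col-0, 897 in Col-aeq, 906 in fad3/7/8 and 487 to 655 in the remaining lines. The contrast alone thus cannot say which control line departed for these genes. Col-0 signals under the filter level for AT2G39920 (11.2 at ambient temperature) and Fes1B (17.9 in the cold) make these sizes uncertain. By limma, 2137 probe sets had an unadjusted p under 0.05. That was more than for fab1 (847), 35S-FAD3 (1702) and fad3/7/8 (1702) and fewer than for fad2 (3470). After adjustment 16 passed, 11 higher and 5 lower. The count was 27 without Col-aeq ambient, 2486 without Col-aeq cold, 1 without Col-0 ambient and 4 without Col-0 cold. AT3G25150 passed without each of these arrays, but the 5 higher genes did not pass without Col-0 ambient (adjusted p 0.171 to 0.342), 4 did not without Col-0 cold (0.0615 to 0.162) and Fes1B (0.103) and AT5G43440 (0.0787) did not without Col-aeq ambient. Without the signal filter Fes1B (0.126), AT4G32340 (0.0889) and AT5G43440 (0.0677) no longer passed.

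**Figure D4:**
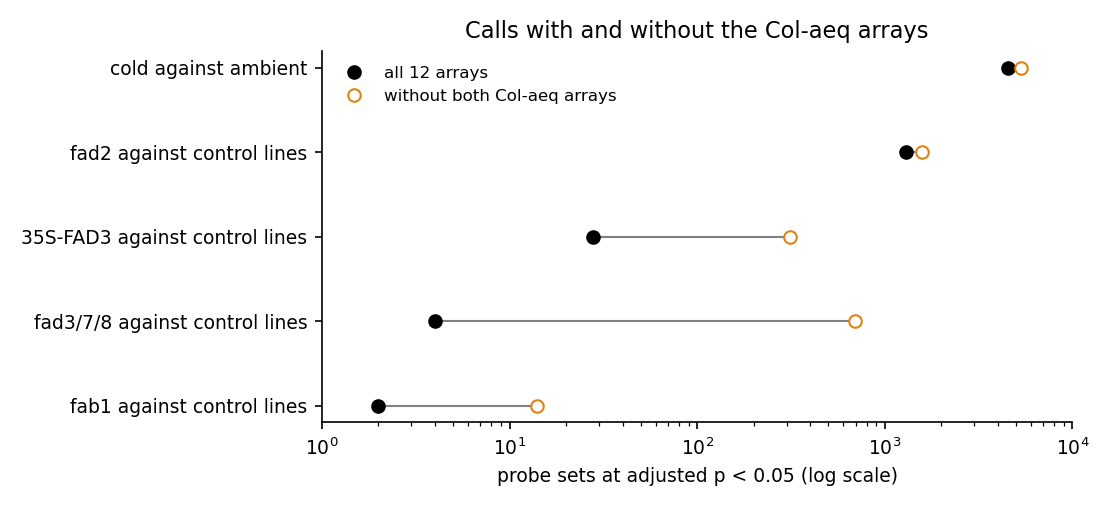
Points give the number of probe sets at an adjusted p under 0.05, on a log axis, with all 12 arrays (black) and without both Col-aeq arrays (orange). The count for fad3/7/8 goes from 4 to 691 and that for cold against ambient from 4538 to 5295.

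The last comparison asked whether lines with altered membrane lipids responded differently to the cold. No gene passed. The lowest p-values for mutants against control lines were those of psbC, a plastid-encoded photosystem II gene (−0.69, SE 0.128), AT1G19960 (1.21, SE 0.253) and AT5G11070 (1.02, SE 0.229), each at an adjusted p of 0.66. For the overexpressor they were those of AT4G24610 (−1.82, SE 0.359), psbC (−0.84, SE 0.171) and AT1G10340 (−2.03, SE 0.419), each at 0.9. COR47 rose by 1.87 in 35S-FAD3 and by 1.25 to 1.43 in the other lines, and the median COR change was 2.86 in Col-0, 2.48 in Col-aeq, 3.46 in fab1, 1.94 in fad2, 2.58 in fad3/7/8 and 3.04 in 35S-FAD3. Over the genes called in the other lines, the slope of the cold change on their mean was 0.946 in Col-0, 0.962 in Col-aeq, 1.04 in fab1, 0.879 in fad2, 0.865 in fad3/7/8 and 0.931 in 35S-FAD3. The mean slope was 0.93 ± 0.1 (SD, n = 3) in mutants and 0.954 in the 2 control lines, which a two-sided exact permutation test did not separate (p = 1, smallest possible p = 0.1). By limma, 0 of 13648 probe sets passed for mutants (1027 at an unadjusted p under 0.05) and 0 for the overexpressor (676, where 682 were expected by chance). Without the Col-0 line, which left Col-aeq as the single control, the counts were 523 and 205; without the Col-aeq line they were 0 and 0. With this design, simulated changes of 1 on the log2 scale were recovered for 34.2% of genes in the mutant comparison and changes of 2 for 98.3%. The simulation gave every array the same spread for a gene. In the data, the SD of the cold change over genes was 0.71 in Col-aeq and 0.52 to 0.60 in the other lines. Recovery may thus be lower in the data. The overexpressor class was 1 line, with its spread taken from the other classes. Its recovery was not simulated, so its lack of calls says little.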

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

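Chosen after the results were seen were the tests of the Col-aeq ambient array as the source of the fad2 calls and of swapped labels in Col-aeq, the look at fad3/7/8 as a second reporter line, and every run without Col-aeq; the lists from gene names were built after the annotation was seen, and the root markers after 12 leading fad2 genes had been seen, leaving these out. In 81 sets of 6 values, 17 had 1 value far from the rest, where chance alone gives about 1 in 20, or 4.05, for separate sets. These sets were not separate, since lists shared genes and several quality measures came from the same arrays, so 4.05 is a rough guide. Of the 17, 11 were in Col-aeq and 6 in other lines.

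The Col-aeq ambient array stood apart in the 3' to 5' ratios of actin (7.00) and GAPDH (1.87), in 25S rRNA signal (2463), in the spiked controls bioC (211, other ambient arrays 103 to 129), bioD (366, against 211 to 263) and cre (2668, against 1747 to 2038), and the Col-aeq cold change had r = 0.649 with the mean of the other lines across genes, against 0.809 to 0.836. Swapped temperature labels in Col-aeq would have given a negative correlation, which the value of 0.649 argues against. Loss of the 5' part of transcripts was taken beforehand to predict that the excess cold change of Col-aeq rises with gene length. Gene length is an indirect measure here, because the distance of the probes from the 3' end was not used. The rank correlation over 7200 genes was 0.308, against −0.154 to −0.0515 in the other lines. For those lines the mean that was subtracted held Col-aeq, which draws their values down, so they are not a separate baseline. A partly degraded RNA sample may thus account for part of the pattern, and the high rRNA and spike signals were not tested further. The ambient array of fad3/7/8, which carries apoaequorin per its titles, had ratios of 2.21 and 1.01, a 25S signal of 158 and r = 0.813, so the reporter was present there without the pattern.

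Against the control lines, fad2 had 1289 calls, and without both Col-aeq arrays 76.5% of these remained, which argues against that array as their main source. A larger share of root tissue would raise root markers alike, and was predicted to put the median of the nuclear photosynthesis genes below 0. That median was 0.00913, so this part was not met. The root markers had a median of 0.777, and the 14 besides PYK10 lay between 0.28 (SE 0.268) and 2.06 (SE 0.305). PYK10, the most abundant at signals of 2231 to 2816, stood at −0.14 ± 0.0966 (SE), while the highest signal of each array was 4043 to 5883, so some compression of PYK10 may remain. PYK10 lay below a bound set beforehand, while 14 of 14 other markers lay above 0. That bound rested on 1 gene whose signal may be compressed, so it cannot decide on a larger share of root tissue. A change in particular root cells stays open too. For genes linked to FAD2, 10 of 107 within 200 genes on each side were called and 616 of 7160 elsewhere, an odds ratio of 1.1 (0.506 to 2.12, Fisher's exact p = 0.729), an interval too wide to decide; the effect of fad2 itself stays open as a hypothesis.

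In other single lines, the cold change of AT2G03750 was −3.29 in 35S-FAD3 (others −2.75 to −2.50), that of COR47 1.87 in 35S-FAD3 (1.25 to 1.43), that of AT5G48570 0.75 in Col-0 (−1.31 to −0.63), that of LHCB4.1 −0.58 in fad2 (−0.30 to −0.15) and that of AT3G05060 1.35 in fab1 (0.19 to 0.59). In Col-aeq, PEX4 changed by 0.25 (0.04 to 0.09), and the list medians were 0.70 for plastid-encoded genes (−0.27 to 0.09), −1.03 for ATG8 genes (−0.63 to −0.45) and 0.15 for endo-1,4-glucanases (−0.23 to −0.11). The bioC spike of the fad2 cold array was 83.4, against 117 to 128 on the other cold arrays.

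With camera, 4 lists differed in their cold change between mutants and control lines, none with an estimated correlation (adjusted p = 0.634 for each). Plastid-encoded genes had a median difference of −0.54 (camera adjusted p = 2.21e-13) and RNA polymerase subunits of 0.36 (0.00999). Without Col-aeq, when Col-0 was the single control, these differences were −0.28 and 0.34. The overexpressor went with the mutants in both lists. Its median cold change was −0.27 for plastid-encoded genes (mutants −0.24 to −0.11, Col-0 0.09, Col-aeq 0.705). For RNA polymerase subunits it was 0.28 (mutants 0.26 to 0.40, Col-0 0.01, Col-aeq 0.11). Averaged over both temperatures, camera ranked these subunits lower than in the control lines in fab1, fad3/7/8 and 35S-FAD3 (adjusted p 0.0166, 0.00321 and 0.00184). In fad2 they did not pass (0.235), and no line passed with an estimated correlation. ATG8 genes differed by 0.23 (camera adjusted p = 0.041) and root markers by −0.42 (0.0102), and without Col-aeq by 0.02 and −0.17. The root marker median was −0.23 in Col-0, −0.23 in fab1, −0.22 in fad2 and −0.16 in 35S-FAD3. It was 0.21 in Col-aeq and −0.76 in fad3/7/8. The Col-aeq array with high 3' to 5' ratios was among the control lines in each of the 4 camera calls.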

How the results depend on the processing

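The runs without both Col-aeq arrays and without the Col-aeq ambient array were chosen after the data were seen. The count for cold stayed within 1.5 times of 4538 in every alternative run (3403 to 5413), as did the direction of the COR median (2.49 to 2.85); with an estimated correlation the COR adjusted p was 0.165 at 2.65 and list calls went from 6 to 0. No paired analysis by replicate number was possible because every array is labelled replicate 1; lines served as the block. Leaving out 1 array gave 1 to 745 calls for fab1, 53 to 3391 for fad2, 3 to 1679 for 35S-FAD3, 0 to 1810 for fad3/7/8 and 1 to 2486 for Col-aeq against Col-0, each highest without Col-aeq cold, when the Col-aeq level rested on its ambient array alone. Leaving out 1 line gave 0 to 523 calls for the cold change of mutants and 0 to 205 for that of the overexpressor, each highest without Col-0. Without a filter, calls were 793 for fad2, 16 for 35S-FAD3 (62.5% higher, against 42.9%) and 2 for fad3/7/8; with the 60th percentile filter, 18 for 35S-FAD3; without an intensity trend, 2 for fad3/7/8 and 8 for Col-aeq. With Col-0 alone as control there were 1 for fab1, 669 for fad2 and 73 for fad3/7/8; with Col-aeq alone, 5 for fab1 and 7 for 35S-FAD3. Without both Col-aeq arrays there were 14 for fab1, 314 for 35S-FAD3 and 691 for fad3/7/8. Centring on the median split the 4 calls of fad3/7/8 into 50% higher, against 75%. FaTA, never past the threshold, reversed from 0.03 to −0.02 without Col-0 and −0.12 without Col-aeq, and was 0.12 without fad3/7/8. Of values for named genes under the alternatives, 530 kept their side of the threshold, 57 lost it and 2 gained it. For filters, fewer or more tests changed the adjustment; otherwise the cause was not tested. Signals near the floor carry little information, and genes under the filter were not assessed.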

Other observations

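The test of a deletion near AT3G25150 and the label swaps were chosen before their results were seen; the lists and the runs without Col-aeq were chosen after the annotation or the array quality had been seen. In the cold, sugar transporters of the SWEET family rose in 5 of 7 tested members, with SWEET13 at 0.98 (SE 0.097), SWEET2 at 0.73 (SE 0.0888) and SWEET1 at 0.70 (SE 0.108), whereas SWEET16, a vacuolar member, fell by 0.62 (SE 0.109). The list median was 0.58 (camera adjusted p = 0.0381; adjusted p = 0.384 with an estimated correlation). Of 31 UDP-glycosyltransferases, 13 rose and 4 fell, with UGT72B3 at 1.43 (SE 0.0912), UGT73C1 at 1.36 (SE 0.159) and UGT71B1 at 0.97 (SE 0.0852) among the rises and UGT85A5 at −0.91 (SE 0.224) among the falls; the median was 0.18 (adjusted p = 0.024; adjusted p = 0.384 with an estimated correlation), and 12 rose after median centring while 3 fell under quantile normalization. Of 10 cytochrome P450 genes of the 71B family, 7 fell and 0 rose by limma, led by CYP71B24 at −0.78 (SE 0.211) and CYP71B29 at −0.70 (SE 0.177), with a median of −0.52 (adjusted p = 0.024; adjusted p = 0.384 with an estimated correlation). Other single genes in the cold were the ubiquitin ligase PUB19 at 2.83 (SE 0.188) and PUB26 at −1.80 (SE 0.165), LEA4-5 at 1.74 (SE 0.235), the light-signalling factor HYH at 1.60 (SE 0.167) and NRPA1 and NRPA2, the large subunits of RNA polymerase I, at 1.17 (SE 0.199) and 0.86 (SE 0.137).

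Without both Col-aeq arrays, when Col-0 was the single control, 14 probe sets passed for fab1, 1585 for fad2, 314 for 35S-FAD3 and 691 for fad3/7/8. AT5G05600, one of the oxygenases that hydroxylate jasmonate, was lower than in Col-0 by −1.78 in fab1 (SE 0.249), −2.13 in fad2 (SE 0.249), −2.68 in 35S-FAD3 (SE 0.249) and −1.65 in fad3/7/8 (SE 0.249). Its signals were 198 and 221 in Col-0, 77.0 and 145 in Col-aeq and 26.0 to 73.7 on the other arrays. AT2G38240, of the same family, was lower in fad2 (−4.43, SE 0.441), fad3/7/8 (−2.63, SE 0.441) and 35S-FAD3 (−2.47, SE 0.441), AT1G10585 in fad2 (−2.66, SE 0.309), 35S-FAD3 (−2.61, SE 0.309) and fad3/7/8 (−2.19, SE 0.309), and the defensin PDF1.2b in fad2 (−2.32, SE 0.5) and fad3/7/8 (−2.05, SE 0.5). All lines were set against the same 2 Col-0 arrays, so part of what they share may come from those arrays. With all arrays 7 of these 12 calls did not pass: AT5G05600 in fab1 (adjusted p = 0.462) and fad3/7/8 (0.21), AT2G38240 in 35S-FAD3 (0.108) and fad3/7/8 (0.181), AT1G10585 in fad3/7/8 (0.138), and PDF1.2b in fad2 (0.0622) and fad3/7/8 (0.298). The 691 calls for fad3/7/8 also confound the mutations with apoaequorin, which Col-0 lacks. The same may hold for the 314 calls for 35S-FAD3, whose genotype label names apoaequorin. Signals of AT2G38240 were 3.6 to 32.7 and those of AT1G10585 11.5 to 40.3 in the altered lines, partly under the filter level, so these sizes are uncertain.

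The loss of AT3G25150 in Col-aeq (−3.32) was the largest named difference between the control lines and held at both temperatures, which loss of 5' ends in the ambient array does not account for alone. A candidate explanation is a deletion at the transgene insertion that spans neighbouring genes. Of the 5 annotated genes on each side, 2 were measured, FaTA at −0.13 (SE 0.265) and AT3G25120 at −0.13 (SE 0.154), a median of −0.129. That leaves a deletion of both genes without evidence, but a bound on 2 genes was too weak a rule, since a smaller deletion, an insertion in the gene or a sequence difference under the probes would spare both. Apart from the deletion, no biological explanation was tested.

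Chance as the source of the cold calls was tested by swapping the temperature labels within lines. Of the 32 ways, counting a full swap as the same split, 1 gave as many calls as the real labels, namely the real labels themselves with 4538, and the highest count among the others was 0. That argues against chance. The swaps do not address causes that differed between all ambient and all cold samples, such as the time of harvest, which is not given in the sources used here.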
